A study of Mus musculus with 6 samples.

How the data were processed

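RNA was taken from brain endothelial cells that had been sorted with magnetic beads straight into lysis buffer and never cultured, per the labels' protocols. Per the same protocols, stranded mRNA libraries were made with the Illumina TruSeq kit and read on a NovaSeq as single-end reads of 100 bp. Per the submitters' processing notes, the authors aligned reads with STAR to GRCm38 and counted them per gene with featureCounts. No versions, gene annotation, strand setting or read filters are given in the sources used here. The deposited files hold raw counts per gene symbol, one file per library with 23329 symbols and no rows without a gene name. The column header calls them matched counts, and the values are whole numbers whose totals differ between libraries. A total of 18 groups of genes, 41 genes in all, had identical counts in all 6 libraries at a total count of at least 100, among them Hba-a1 and Hba-a2. The counts of near-identical genes therefore cannot be told apart, and 2 of these 41 genes are among the calls.

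Samples were grouped by the genotype label, 3 WT and 3 GLUT1EC-/-. Symbols were matched to the RefSeq table of GRCm38: 20748 were current symbols, 2360 were found only as synonyms and 221 were in neither. Coordinates and exon overlaps come from GENCODE M21 on GRCm38, in which 103 of the 105 named genes were placed. Of these, 2 share exon positions with another coding gene on the same strand (Ctsd and Gbp4) and 7 with one on the other strand, among them Gapdh. With no strand setting stated, these counts are uncertain. The 3 replicates of a group are separate animals by their numbers. The labels do not say which animals share a litter, and no pairing was used.

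The main test was edgeR 4.0.16's quasi-likelihood F test under R 4.3.3, fitted to all 6 libraries with genotype as the only term, TMM scaling, filterByExpr (minimum count 10, minimum total 15) and robust dispersion estimates. It left 14838 genes, with a biological coefficient of variation of 23.2%. P-values were adjusted by the Benjamini-Hochberg method over these genes, at a threshold of 0.05. Levels are CPM, counts scaled to library size with the TMM factors, and are given as mean ± SD over 3 libraries, and standard errors of log2 fold changes are the fold change divided by the square root of F. A fold for a gene with 0 counts in a group was set against a floor of 3 counts per library. Intervals and floors cover these libraries only, and PCR reads without molecular identifiers are not independent molecules. Bootstrap intervals of list medians resample genes, not animals, so they do not measure the spread between animals. Gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01, and again with an estimated one) and with fry, each adjusted over 43 lists. The edgeR p-values measure the spread between 3 animals per group. Those of camera compare a list's genes with other genes, and the preset correlation takes genes as nearly independent. The estimated correlation was 0.83 for microglia markers and 0.095 for interferon-stimulated genes, so camera p-values with the preset one do not measure the spread between animals.

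The lists, the design and the alternatives were fixed before the data were examined. Named genes are Slc2a1, the 10 largest fitted rises and the 10 largest falls among called genes with a mean of at least 1 CPM and groups that do not overlap, and per list up to 4 called members by adjusted p, or the 2 most abundant where none was called. Predicted genes were skipped when naming. One gene that the rule names is not reported here. Lists for glucocorticoid targets, disease-associated microglia, and non-classical monocytes and NK cells were written after the results had been seen, as was the alternative with sex as a term. Sex was read from the counts of Xist and Ddx3y, which put WT 3 and GLUT1EC-/- 3 as male and the other 4 libraries as female. The other alternatives were RLE and upper-quartile scaling, library size alone, DESeq2 1.42.0, limma-voom, non-robust dispersion, no filter on low counts, at least 1 CPM in 3 libraries, the animal number series as a term, each library left out in turn, an adjusted p of 0.1 and glmTreat with a fold of 1.2.

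The tests were tried on simulated counts for the 14838 genes with the real means and library sizes, 200 of them changed. Each gene was given the dispersion of the fitted trend, not its own, and no library was made to stand apart. Recovery and false calls in the real data may therefore differ. At 4-fold, 2-fold and 1.5-fold, edgeR recovered 94.9%, 58.6% and 9.64% of the changed genes, with 2.97% false calls. Limma-voom gave 4.95% false calls and DESeq2 13.2%, above its nominal level. For lists, camera and fry each called 3 of 3 shifted lists and 0 of 40 others, in counts simulated without correlation between genes. Changes of 1.5-fold are thus mostly out of reach here, and a gene without a call may have changed by that much.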

Results

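Gene expression was measured by RNA sequencing in endothelial cells isolated from the brains of adult C57BL/6 mice, 8 weeks old, with magnetic bead sorting (MACS). Slc2a1 encodes GLUT1, the main glucose carrier of the blood-brain barrier. The comparison asked how the transcriptome of brain endothelial cells differs between mice with an endothelial-cell-specific knockout of this gene, labelled GLUT1EC-/-, and wild-type (WT) littermates. Each group held 3 libraries, each with its own animal number in the labels. The cells had not been cultured. Total counts were 31874662, 33887825 and 39424384 in WT 1 to 3 and 37408507, 37868681 and 35323299 in GLUT1EC-/- 1 to 3, and each library had counts for 16705 to 17257 genes. The 10 most abundant genes took 4.82% to 5.42% of the counts of each library. GLUT1EC-/- 2 stood apart: its log counts correlated with those of its own group at a mean r of 0.964 across genes, against 0.972 to 0.989 for the other 5 libraries, and its TMM scaling factor was 0.884 against 1.01 to 1.05. GLUT1EC-/- 3 had a mean r of 0.973 to the WT libraries and 0.972 to its own group. Genes are not independent replicates, so these correlations only describe the libraries. No pair of libraries of a group agreed within counting noise, with chi-square values of 12.2 to 182 per degree of freedom.

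Slc2a1 lies on the plus strand of chromosome 4 (GRCm38, 119108711 to 119137983), has 10 exons in its longest annotated transcript and overlaps the exons of no other coding gene. Its expression did not differ between the groups by more than the spread between libraries. The count was 4212 ± 250 CPM, the count scaled to library size, in WT and 4348 ± 927 CPM in the libraries labelled GLUT1EC-/- (SD, n = 3 each). By library it was 3984, 4479 and 4172 CPM in WT and 3735, 5414 and 3893 CPM in the libraries labelled GLUT1EC-/-. The log2 fold change was 0.05 (SE 0.18, edgeR adjusted p = 0.921), a fold of 1.03 with a 95% interval of 0.780 to 1.37, which allows a fall of at most 22.0%. Leaving out GLUT1EC-/- 2 gave a log2 fold change of -0.15 (edgeR adjusted p = 0.553). The count of the targeted gene therefore does not separate the groups, and every direction given here is between libraries as labelled. The labels do not say which exons were deleted, and a count over the whole gene does not tell shortened transcripts from complete ones.

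**Figure D1:**
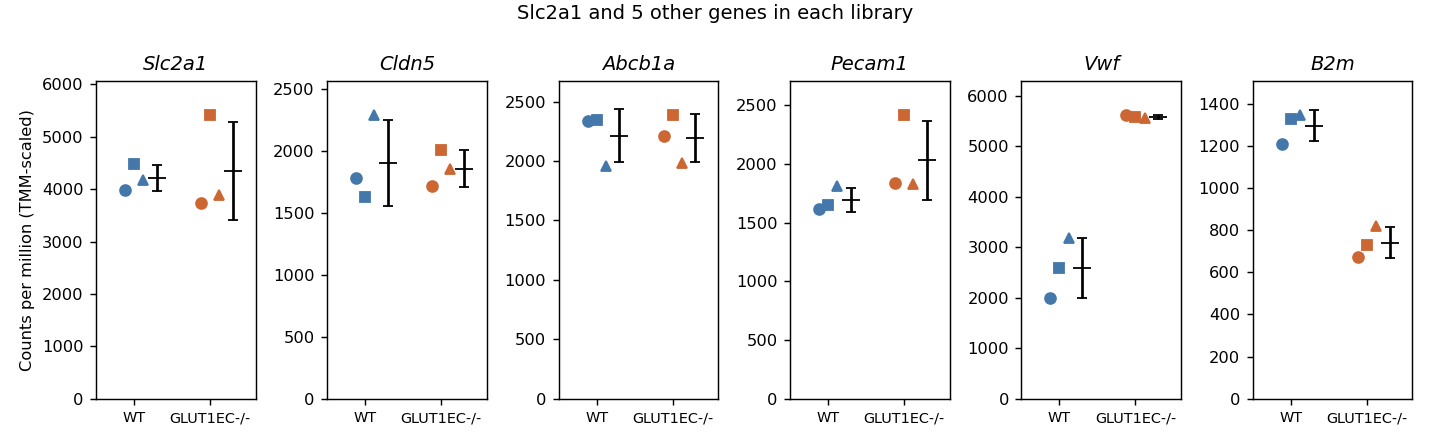
Expression of Slc2a1, Cldn5, Abcb1a, Pecam1, Vwf and B2m in TMM-scaled CPM, on linear axes from 0, in the 3 WT (blue) and the 3 libraries labelled GLUT1EC-/- (orange); circles, squares and triangles are replicates 1, 2 and 3, and black marks give the mean and SD. Slc2a1 had means of 4212 and 4348 CPM, Vwf was higher in all 3 labelled knockout libraries (2590 against 5584 CPM) and B2m was lower in all 3 (1296 against 740 CPM).

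Of 14838 genes tested, 194 differed between the groups, 128 higher and 66 lower in the libraries labelled GLUT1EC-/- (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 113 rose and 56 fell by at least 2-fold. Among the fixed lists, 6 of 14 basement membrane genes and 3 of 15 microglia markers rose, and 7 of 24 interferon-stimulated and 3 of 19 antigen presentation genes fell. These 4 lists passed as sets with a preset correlation and not with an estimated one (adjusted p = 0.767, 0.917, 0.258 and 0.258). The 194 genes include no member of the fixed lists for glycolysis, barrier transporters or junctions. All 194 had groups that did not overlap, as did 3401 of the 14838 tested genes (22.9%, against 10% by chance). The number of calls depended on single libraries: it was 0 without WT 1, 1 without WT 2, 5 without WT 3, 32 without GLUT1EC-/- 1 and 862 without GLUT1EC-/- 2. Without GLUT1EC-/- 3 the number was 283, with 178 higher and 105 lower, against 128 and 66 with all libraries. Animal numbers fall into the 200s (2 WT, 1 GLUT1EC-/-) and the 500s (1 WT, 2 GLUT1EC-/-), and with this series as a term 14 genes passed. Nothing in the labels says what the number series stands for.

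More genes were called higher in the basement membrane and matrix list than in any other fixed list. Of its 14 tested members, 6 rose, 0 fell and 8 did not pass; adjusted over the list alone, 7 rose. Fn1, the gene of the matrix protein fibronectin, went from 4723 ± 296 to 8932 ± 664 CPM (log2 fold change 0.92, SE 0.14, edgeR adjusted p = 0.0259). Col18a1, a collagen of vascular basement membranes, rose by 1.14 on the log2 scale (edgeR adjusted p = 0.0259) and Nid1, which links laminin to collagen IV, by 1.03 (edgeR adjusted p = 0.016). Sparc, a collagen-binding matrix protein, went from 1353 ± 34 to 2594 ± 303 CPM (edgeR adjusted p = 0.0259). As a set the list moved up against other genes (camera adjusted p = 4.32e-05 with a preset correlation), and its adjusted p was 0.767 with an estimated correlation. Its median log2 fold change was 0.57, and 0.44 and 0.70 within the 200s and the 500s. Fibroblast markers moved with it: Dcn, a small matrix proteoglycan, rose from 19.5 ± 1.2 to 79.8 ± 20.3 CPM (log2 fold change 2.03, edgeR adjusted p = 0.00997). Dcn was the 1 of 10 fibroblast markers to pass over all genes, 9 rose adjusted over the list alone, and the set had a camera adjusted p of 0.000155 (adjusted p = 0.793 with an estimated correlation), with a median of 1.16, and 1.14 and 0.87 within the number series. Without GLUT1EC-/- 3 the fibroblast median was 0.67.

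Interferon-stimulated genes were lower in the libraries labelled GLUT1EC-/-. Of 24 tested, 0 rose, 7 fell and 17 did not pass; adjusted over the list alone, 16 fell. Gbp3 and Gbp4, interferon-inducible GTPases, fell by 1.31 (edgeR adjusted p = 0.0164) and 1.32 (edgeR adjusted p = 0.0407) on the log2 scale. Rsad2, the antiviral protein viperin, fell by 1.14 (edgeR adjusted p = 0.024) and Cmpk2, a mitochondrial nucleotide kinase gene next to it on chromosome 12, by 1.11 (edgeR adjusted p = 0.0206). Gbp4 shares exon positions on its strand with 2 other annotated Gbp genes, so its count is uncertain. The median log2 fold change of the list was -0.81, and -0.93 and -0.80 within the 200s and the 500s (camera adjusted p = 3.43e-13, and adjusted p = 0.258 with an estimated correlation). Antigen presentation genes went the same way, with 3 of 19 falling, 16 not passing and 13 falling adjusted over the list alone. B2m, the light chain of MHC class I, went from 1296 ± 74 to 740 ± 72 CPM, a log2 fold change of -0.81 (SE 0.14, edgeR adjusted p = 0.0386). The immunoproteasome subunits Psmb10 and Psmb8 fell by 0.89 (edgeR adjusted p = 0.0485) and 0.76 (edgeR adjusted p = 0.0499). The antigen presentation set had a median of -0.60, and -0.71 and -0.80 within the number series (camera adjusted p = 5.84e-10, and adjusted p = 0.258 with an estimated correlation). Lymphocyte markers moved with both lists, with a median of -0.88 and Cd79a, part of the B cell receptor, falling from 6.1 ± 0.6 to 2.1 ± 0.2 CPM (log2 fold change -1.54, edgeR adjusted p = 0.0232). Cd79a was the 1 of 12 lymphocyte markers to pass over all genes, 4 fell adjusted over the list alone, and the set had a camera adjusted p of 6.44e-06 (adjusted p = 0.793 with an estimated correlation). Within the number series the lymphocyte median was -0.21 in the 200s and -1.78 in the 500s, and it was -1.35 without GLUT1EC-/- 1 and -0.56 without GLUT1EC-/- 3.

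Microglia markers were higher in the libraries labelled GLUT1EC-/-. Of 15 tested, 3 rose, 0 fell and 12 did not pass; adjusted over the list alone, 8 rose. The complement genes C1qc and C1qb went from 63.6 ± 5.0 to 211 ± 56 CPM (log2 fold change 1.73, edgeR adjusted p = 0.0148) and from 69.1 ± 16.9 to 194 ± 66 CPM (log2 fold change 1.49, edgeR adjusted p = 0.0432). Trem2, a lipid-sensing receptor of microglia, had a log2 fold change of 1.45 (SE 0.23, edgeR adjusted p = 0.0316). The median of the list was 0.96, with 0.96 and 0.73 within the 200s and the 500s (camera adjusted p = 0.00011, and adjusted p = 0.917 with an estimated correlation). Without GLUT1EC-/- 3 it was 0.55 (camera adjusted p = 0.0254). Gfap, the intermediate filament of reactive astrocytes, rose from 5.6 ± 0.2 to 44.3 ± 13.4 CPM (log2 fold change 2.97, SE 0.23, edgeR adjusted p = 0.00669). It was the 1 of 12 astrocyte markers to pass over all genes, with 2 rising adjusted over the list alone and a median of 0.07. The 10 oligodendrocyte markers had a median of -0.24 and did not pass as a set (camera adjusted p = 0.255). By value 8 of them were lower and 2 higher. Their summed level went the other way from the median, with means of 879 CPM in WT and 2133 CPM in the libraries labelled GLUT1EC-/-, a difference that was not tested. No marker passed for pericytes (0 of 11), smooth muscle (0 of 8), neurons (0 of 11), oligodendrocyte precursors (0 of 6), macrophages and monocytes (0 of 11), neutrophils (0 of 4), erythroid cells (0 of 4) or the choroid plexus (0 of 9). Adjusted over the list alone, 2 macrophage and monocyte markers rose and 4 fell. All 4 erythroid genes were lower by value, with a median of -0.76 (camera adjusted p = 0.105), though Hba-a1 and Hba-a2 share their counts. Within the number series the erythroid median was 0.49 in the 200s and -2.36 in the 500s. Beta-s, a beta globin gene, was at 372, 347 and 463 CPM in WT and 442, 32.7 and 168 CPM in GLUT1EC-/- 1 to 3. Ttr, the abundant choroid plexus transcript, was at 4443 ± 1424 and 4072 ± 1161 CPM.

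Endothelial identity genes did not pass as a set, with a median of 0.02, and 1 of 19 rose. That gene was Vwf, von Willebrand factor, which went from 2590 ± 602 to 5584 ± 34 CPM (log2 fold change 1.11, SE 0.19, edgeR adjusted p = 0.0372). Of 14 arterial genes, 2 rose and 1 fell, with 4 and 2 adjusted over the list alone, and the set did not pass. Mgp and Fbln5, both linked to elastic fibres and arterial matrix, rose by 1.40 (edgeR adjusted p = 0.0207) and 1.33 (edgeR adjusted p = 0.0407) on the log2 scale. Gkn3, a marker of brain arterial endothelium, fell from 170 ± 31 to 14.0 ± 10.1 CPM (log2 fold change -3.59, SE 0.55, edgeR adjusted p = 0.0269). Junction genes (0 of 20), barrier transporters (0 of 20), caveolae genes (0 of 9), Wnt pathway genes (0 of 19), endothelial inflammatory genes (0 of 22), tip cell genes (0 of 18) and venous genes (0 of 9) had no member past the threshold. Adjusted over the list alone, 5 tip cell genes rose and 3 fell, 1 venous gene rose, and 1 endothelial identity gene rose and 1 fell. Cldn5, the main tight junction claudin, had a log2 fold change of -0.03 (SE 0.17), and Abcb1a, the efflux pump P-glycoprotein, of -0.01 (SE 0.15).

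Genes of glucose metabolism gave no call. None of 11 other glucose and hexose transporters, 21 glycolysis genes, 8 pentose phosphate genes, 13 hexosamine genes or 5 genes of the glucose-sensing MondoA axis passed. Gapdh was at 440 ± 34 and 550 ± 55 CPM (log2 fold change 0.32, SE 0.14, edgeR adjusted p = 0.34) and Txnip, which glucose induces, at 624 ± 51 and 912 ± 524 CPM (edgeR adjusted p = 0.514). No member passed among 19 TCA cycle, 19 fatty acid oxidation, 9 ketone and monocarboxylate, 11 glutamine, 25 ATF4 target, 20 unfolded protein response, 13 p53 or 24 cholesterol genes; adjusted over the list alone, 1 p53 gene rose. The 67 oxidative phosphorylation genes had 0 calls and a median log2 fold change of 0.15 (camera adjusted p = 0.000705, and adjusted p = 0.917 with an estimated correlation; 0.0698 without GLUT1EC-/- 3), or 0.12 and 0.06 within the 200s and the 500s. Angptl4, a lipoprotein lipase inhibitor on the hypoxia list, rose from 24.6 ± 7.1 to 89.4 ± 37.9 CPM (log2 fold change 1.86, edgeR adjusted p = 0.0494), as the 1 of 17 hypoxia genes to pass, also adjusted over the list alone. Ctsd, a lysosomal protease, rose from 614 ± 49 to 1439 ± 330 CPM (log2 fold change 1.23, edgeR adjusted p = 0.0259), the 1 of 19 lysosome and autophagy genes to pass, with 4 rising adjusted over the list alone; its exons overlap another annotated coding gene on the same strand, so its count is uncertain. Immediate early and heat shock genes had 0 of 20 called, 3 falling adjusted over the list alone, and a median of -0.28, with -0.45 and -0.31 within the number series and -0.46 without GLUT1EC-/- 2 (camera adjusted p = 0.000128, and adjusted p = 0.793 with an estimated correlation). Their most abundant members, Fosb and Egr1, were at 5729 ± 893 against 5151 ± 1252 CPM and at 6158 ± 929 against 4431 ± 357 CPM.

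Among proliferation genes, Mki67, the source of the Ki-67 antigen, rose from 3.2 ± 1.2 to 20.1 ± 8.1 CPM (log2 fold change 2.65, edgeR adjusted p = 0.0242). It was the 1 of 26 to pass over all genes, and 17 rose adjusted over the list alone. The list had a median of 1.51, with 1.97 and 0.89 within the 200s and the 500s (camera adjusted p = 3.19e-09, and adjusted p = 0.793 with an estimated correlation). Kif15, a mitotic kinesin, had a log2 fold change of 3.67 (edgeR adjusted p = 0.0164).

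Of the 10 largest rises over all genes, Mmp3, a matrix metalloproteinase, had 0 counts in the 3 WT libraries and 9.74 ± 10.2 CPM in the libraries labelled GLUT1EC-/-, at least 115-fold higher against a floor of 3 counts per WT library (edgeR adjusted p = 0.0476). GLUT1EC-/- 2 held 21.3 CPM of Mmp3, and without it the bound was 46.5-fold. Saa3, an acute phase protein, had a log2 fold change of 6.75 (SE 1.10), and Spp1, osteopontin, went from 5.0 ± 1.1 to 191 ± 129 CPM (log2 fold change 5.25, edgeR adjusted p = 0.00997). Gpnmb and Cst7, known from phagocytic and activated myeloid cells, rose by 5.88 and 3.80 on the log2 scale (edgeR adjusted p = 0.00669 and 0.0164). Igfbp4, a secreted binding protein of insulin-like growth factors, went from 82.6 ± 16.9 to 789 ± 418 CPM (log2 fold change 3.25, edgeR adjusted p = 0.016). Fkbp5, a glucocorticoid-induced chaperone partner, was at 52.4, 211 and 78.9 CPM against 8.9 to 11.7 CPM in WT (log2 fold change 3.44, edgeR adjusted p = 0.0224). Hhipl1 and the fibril-associated collagen Col12a1 had log2 fold changes of 4.12 and 3.25. The largest falls were those of Cd300e, Emr4 (now Adgre4) and Treml4, all known as receptors of myeloid cells, which had log2 fold changes of -5.69, -5.49 and -5.43 (edgeR adjusted p = 0.012, 0.0151 and 0.0164), from means of 6.8, 11.6 and 12.3 CPM. Ear2, Ear3 and Ear12, which belong to a family of near-identical ribonucleases, had log2 fold changes of -3.65, -3.57 and -3.57, and Ear3 and Ear12 had the same count in every library, so they cannot be counted apart. Itgal, the leukocyte integrin chain CD11a, fell from 57.1 ± 31.2 to 5.9 ± 3.5 CPM (edgeR adjusted p = 0.0316). S1pr5 and the collagen gene Col14a1 had log2 fold changes of -3.39 and -3.15. Single libraries moved some of these folds by over 1.5 times: the log2 fold change was 4.54 for Spp1 and -4.24 for Gkn3 without GLUT1EC-/- 3, 2.63 for Fkbp5 and 3.46 for Hhipl1 without GLUT1EC-/- 2, and -6.51 for Cd300e, -6.19 for Emr4, -6.27 for Treml4 and -3.87 for Itgal without GLUT1EC-/- 1. Treml4 was at -4.75 without WT 2 and Saa3 at 6.11 without WT 3. Saa3 had counts in WT 2 alone among the WT libraries, 10 in all, so its fold is uncertain.

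**Figure D2:**
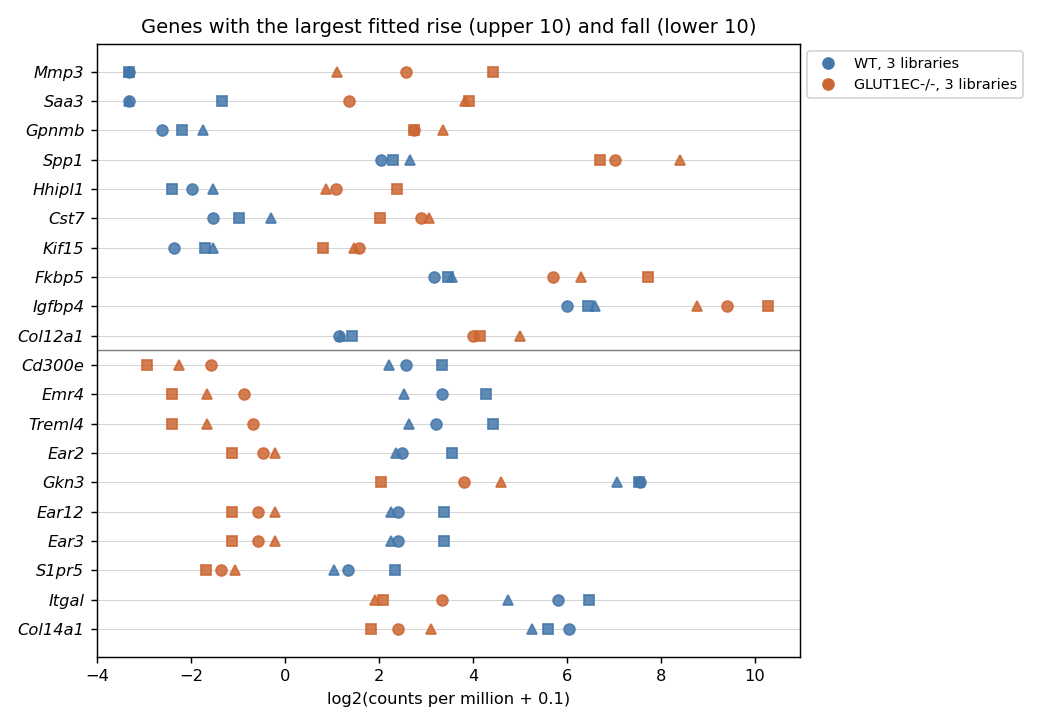
Expression of the 10 genes with the largest fitted rise (upper part) and the 10 with the largest fitted fall (lower part), as log2 of TMM-scaled CPM plus 0.1, in each of the 3 WT (blue) and the 3 libraries labelled GLUT1EC-/- (orange); circles, squares and triangles are replicates 1, 2 and 3. For all 20 genes the groups do not overlap, which the rule for choosing them required, and Mmp3 has 0 counts in the 3 WT libraries.

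**Figure D3:**
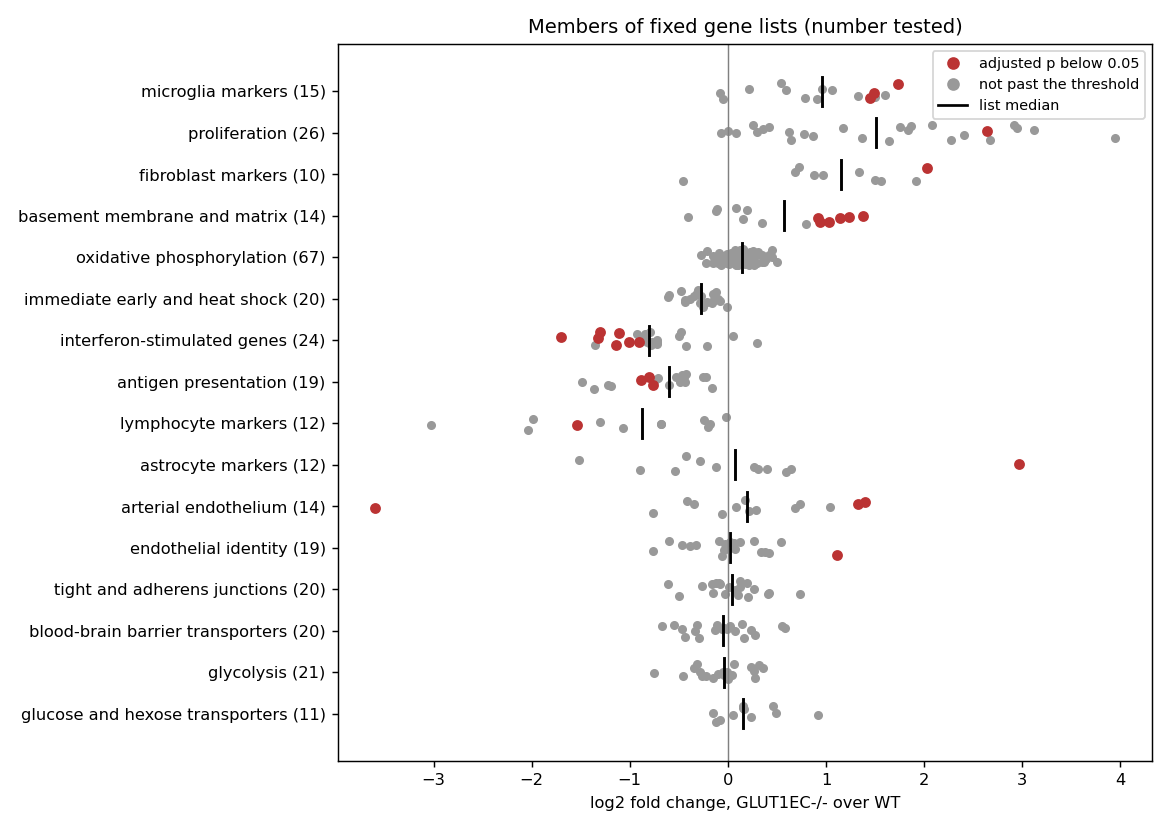
Log2 fold change of the members of 16 gene lists, libraries labelled GLUT1EC-/- over WT; each point is a gene, red where edgeR's adjusted p is under 0.05, and the black bar is the list's median. Interferon-stimulated genes (24, median -0.81) and antigen presentation genes (19, median -0.60) lie to the left, microglia markers (15, median 0.96) and basement membrane genes (14, median 0.57) to the right, and glycolysis (21, median -0.04) and barrier transporter genes (20, median -0.05) around 0.

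Of 43 lists tested, 9 passed with camera's preset correlation, 5 up and 4 down, 0 passed with an estimated correlation, and 3 passed with fry, which asks whether a list's genes move one way on balance: interferon-stimulated, antigen presentation and basement membrane genes. The median, the mean and the test differed in sign for the MondoA axis (median -0.03, mean 0.22, test up), the hypoxia list (-0.01, 0.06, up), macrophage and monocyte markers (0.21, -0.16, down), tip cell genes (-0.11, 0.07, down), neuron markers (-0.12, 0.04, down) and the ketone list (median -0.19, test up), and none of these lists passed.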

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

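One alternative, sex as a term, was chosen after seeing the data. All 194 calls kept their sign and an unadjusted p under 0.05 in each of the 18 alternatives that tested them, and 187 were tested at a minimum of 1 CPM in 3 libraries. These genes were chosen by their p in the same libraries that the alternatives refit, so this outcome was largely set by the choice. The count of calls was 879 (502 higher, 377 lower) with DESeq2, whose false share was the highest on simulated counts; 14 (9 and 5) with the animal number series as a term; 113 (75 and 38) with sex as a term; 119 (80 and 39) with glmTreat at a fold of 1.2; and 429 (262 and 167) at an adjusted p of 0.1. The other scalings and filters, limma-voom and non-robust dispersion gave 138 to 246. Leaving out each library in turn gave 0 to 862 calls, 0 to 530 higher and 0 to 332 lower. The 0 without WT 1 stands beside 1248 genes at an unadjusted p under 0.05. Of the 44 named genes with a call, 8 kept it with the number series, 30 with sex, 0 without WT 1, 0 without WT 2, 1 without WT 3, 13, 41 and 42 without GLUT1EC-/- 1, 2 and 3, and 35 to 44 elsewhere. A fit on 5 libraries has fewer samples, and a term costs a degree of freedom; beyond that the cause was not tested.

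Slc2a1 was without a call in all alternatives. The Slc2a1 log2 fold change was -0.000927 with upper-quartile scaling, -0.020 with library size alone and -0.011 with the number series, and -0.15 to 0.14 with each library left out. The 9 list calls held in the other scalings, filters, terms and left-out libraries, save oxidative phosphorylation without GLUT1EC-/- 3. Camera with an estimated correlation called 0 lists and fry 3.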

Other observations

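Further genes stand out whose choice followed their values. Lower in the libraries labelled GLUT1EC-/- were Alpl, alkaline phosphatase of brain capillaries, at 498 ± 40 against 119 ± 41 CPM (edgeR adjusted p = 0.0164), and the chemokine gene Cxcl12 at 1404 ± 325 against 564 ± 17 CPM (edgeR adjusted p = 0.0206). Igfbp7, Ace and Ctgf were higher, with Igfbp7 at 1015 ± 255 against 3049 ± 860 CPM (edgeR adjusted p = 0.0296). Hif3a was at 4.5 ± 1.3 against 30.7 ± 6.4 CPM (edgeR adjusted p = 0.0115). The clock output gene Dbp, with 83.4 ± 39.2 against 23.9 ± 12.1 CPM, did not pass (edgeR adjusted p = 0.122).

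The tests of the transcript level, of cell shares, of microglia, of leukocytes and of glucocorticoid targets were chosen after the results they bear on had been seen. The tests of a wrong label and of the number series and the other splits were set beforehand.

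With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 194 calls and the highest of the others 0, so 1 of 10 reached the real count, and the same held for the higher and the lower calls. For lists it was 4 of 10, with 9 real calls and up to 14 in another split, that of WT 1, WT 2 and GLUT1EC-/- 2 against the rest; the camera calls with a preset correlation therefore do not stand above regrouped libraries.

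Slc2a1 is not lower in the libraries labelled GLUT1EC-/-. A loss of most of its transcript is argued against by the lower end of its fold interval, 0.780. A single wrong label is argued against by the 200 genes ranked highest without each library, of which 69% (GLUT1EC-/- 2) to 98.5% lay closer to its own group. For GLUT1EC-/- 3 it was 74%, although its mean r over all genes was 0.973 to WT and 0.972 to its own group. These genes separate the libraries as labelled and do not read the Slc2a1 allele itself. Several wrong labels at once were not tested with these genes. Slc2a1 ran from 3735 to 5414 CPM over the 6 libraries. No exchange of labels among them would therefore give a group that lost most of the transcript. Every other split of the libraries into 3 and 3 gave 0 calls, against 194 for the labels. Wrong labels other than an exchange among these libraries stay open. A joint rise of neurons, astrocytes, oligodendrocytes, pericytes, smooth muscle and choroid plexus that could carry the transcript is argued against by the median of their 61 markers. It was -0.071 (95% bootstrap interval over genes -0.12 to 0.18). A pooled median cannot tell whether a single one of these types rose. By type, medians ran from -0.24 for oligodendrocytes to 0.18 for pericytes. The summed level of the oligodendrocyte markers was nevertheless higher in the libraries labelled GLUT1EC-/-, with means of 2133 against 879 CPM. The explanation was narrowed to these cell types after the pooled value was seen, so microglia and fibroblasts stay open. A deletion that leaves most of the transcript countable stays open and was not tested.

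Microglia genes are higher by their median, with 3 of 15 called. As a set they had an adjusted p of 0.917 by camera with an estimated correlation and 0.362 by fry. More microglia in an unchanged state are argued against by the spread of their 15 markers, which did not move by a common shift (Cochran Q of 70.0 with 14 degrees of freedom, 42.5 without WT 2, 44.0 without WT 1 and 169 without GLUT1EC-/- 2). A lower endothelial share would raise all other cell types alike. The microglia median exceeded that of the 61 neuron, astrocyte, oligodendrocyte, pericyte, smooth muscle and choroid plexus markers by 1.03 (95% bootstrap interval over genes 0.52 to 1.56). Without GLUT1EC-/- 3 the difference was 0.69 (0.04 to 1.15). The microglia median did not exceed that of fibroblast markers, at 1.16. In these libraries the types thus did not rise alike. The intervals resample genes, and the 15 microglia markers had an estimated correlation of 0.83. They therefore do not show that the difference holds between animals. A move to a disease-associated state stays open: 16 further genes of that state had a camera p of 0.0778, 0.362 with an estimated correlation and 0.0496 without GLUT1EC-/- 2. The cells were sorted for endothelium, and an effect of genotype stays open as a hypothesis.

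Interferon-stimulated and antigen presentation genes are lower by their medians, with 7 of 24 and 3 of 19 called. Each set had an adjusted p of 0.258 by camera with an estimated correlation. By fry the adjusted p was 0.029 and 0.0344. The number series as the whole cause is argued against by the list's median with the series as a term, -0.88 (-0.93 to -0.76). Fewer blood leukocytes may contribute: Ptprc, carried by nearly all leukocytes, had a log2 fold change of -1.10 (SE 0.30, edgeR adjusted p = 0.139), which neither passes nor lies clear of the list's median. A list of 16 non-classical monocyte and NK genes, written after Cd300e and Treml4 were seen, had a median of -0.07 and a camera p of 0.61, with 1 gene rising, Ace. Its members went both ways, 8 of them higher by value, with log2 fold changes from -2.95 for Spn to 1.19 for Ncf1. The median therefore does not show that these cells stayed unchanged. An effect of genotype stays open as a hypothesis.

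The rise of Fkbp5 and Hif3a led to the hypothesis of stronger glucocorticoid signalling. Fkbp5 was higher in each library labelled GLUT1EC-/-, but the shift of 18 further target genes rests on 1 library: they had a median of 0.38 and a camera p of 0.00264 (0.366 with an estimated correlation), against -0.12 and 0.919 without GLUT1EC-/- 2. No call was reached for any of the 18.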
